A study of Rattus norvegicus with 80 samples.

How the data were processed

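RNA from the lungs of male Sprague-Dawley rats was measured on Agilent one-colour (Cy3) rat arrays, 80 in all, covering 4 materials, 4 dose levels and 5 days, with 1 array in each group. The images were read with Agilent Feature Extraction 12.0.3.1 per the labels. The deposited values are log2 values that the authors had normalized and centred on each probe before deposit. The base of the logarithm was not stated and was taken as 2. The largest range of 1 probe over the arrays was 10.61, the median range 1.68 and the median absolute probe median 0.0177. The single files and the series table held the same values (largest difference 0.0). Signal levels, detection calls, slides and scan dates were not among the values used here, so depth could not be given per array. Precision is given instead by the median SE, which was 0.117 for a dose effect over 5 days and 0.166 for a difference between materials.

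Each array had 41103 probes. The 91 control spots were set apart, leaving 41012 rat probes. Of these 20932 carried 1 gene symbol and 20080 none. Symbols were brought to current names through accessions for 17415 probes and through synonyms for 396, 3113 were already current, and 8 kept the platform name. The probes of a gene were averaged, which gave 15924 genes, 3910 of them with more than 1 probe. The plan had been to keep the probe with the highest mean, but centred values hold no level, so that rule became an alternative.

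Tests used limma 3.58.1 in R 4.3.3 with lmFit and eBayes, trend and robust off, and Benjamini-Hochberg adjustment over genes at 0.05. A dose response was the slope over 4 dose levels on 1 day, in log2 per mg/kg, fitted for each of the 20 sets of a material and a day (40 residual degrees of freedom). The change to day 90 was the slope on day 90 minus that on day 1. A dose effect was the mean over 5 days of an exposed array against the vehicle of its own material (48 residual degrees of freedom), and differences between materials were differences of the 2.0 mg/kg effects. The 4 vehicles were compared by an F test with days as blocks (12 residual degrees of freedom). With 1 array per group, p-values measure scatter between these arrays, each 1 rat or a pool.

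Whole lists were tested with camera at a preset correlation of 0.01, adjusted over 44 gene lists and the comparisons of a family (528 tests for dose effects), and again with an estimated correlation and with fry. Lists were written before the data were examined. Named genes followed a rule fixed then too. For each material it took, among called genes on the same side of the vehicle on all 5 days at 2.0 mg/kg, the 6 largest rises and 4 largest falls. For each day it took the 3 largest rises and 2 largest falls by slope, for each pair of materials the 4 largest and 3 smallest differences, for the vehicles the 6 smallest p, and in each list up to 4 members with the smallest p. Symbols that are only identifiers were passed over. The rule did not cover the change to day 90, for which 8 genes with the smallest p were named.

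The 27 spike-in and negative spots were fitted in the same way, and 3 factors of them, or 4 of all control spots, were added to the fits as alternatives. Other alternatives were quantile normalization, testing every probe, a fold of at least 2, the probe with the highest mean, a common control of the 4 vehicles, each material alone, dose as a rank, the mean of the 3 exposed arrays, the 2.0 mg/kg and vehicle arrays alone, and leaving out each dose or day. Doses and materials were reassigned at random in 100 draws, the real one included.

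The methods were tested on simulated data in which 100 of 15924 genes were changed at each fold. At 2-fold and 4-fold, 90% and 99% were recovered for the CNF1 effect of 2.0 mg/kg, 69% and 99% for MWCNT against CNF1, and 37% and 73% for the CNF1 dose response on day 3. The change to day 90 for MWCNT gave 24% and 58%, and the vehicles 83% and 100%. Wrong calls numbered 10, 5, 4, 4 and 9, which holds for simulated noise only. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.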

Results

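Gene expression was profiled in the lungs of male Sprague-Dawley rats, an outbred laboratory strain, after particles had been placed in the airways through the trachea. The particles were 3 preparations of cellulose nanofibrils, which are fine fibres of cellulose and are called CNF1, CNF2 and CNF3, or multi-walled carbon nanotubes (MWCNT), which are nested tubes of carbon. Each material had its own vehicle, distilled water with preservatives. The 80 arrays covered 4 materials, 4 dose levels (vehicle, then 0.5, 1.0, 2.0 mg/kg) and 5 days after instillation (1, 3, 7, 30 and 90), with 1 array in each of the 80 groups. No group had a replicate array, so every test below measured effects against the scatter of arrays around a fitted model, which includes curvature with dose and, for effects over 5 days, change with time. Array descriptions ended in a replicate number of 4 (73 arrays) or 3 (7 arrays), the protocol named 4 rats per group and day, and the labels did not say whether an array held RNA of 1 rat or a pool. The treatment protocol named a dose of 1 mg/kg and suspensions of 0.5, 1.0 or 2.0 mg/mL. The array labels gave these last 3 values as mg/kg, and doses are written that way here. The values were log2 values centred per probe, 41103 probes per array, of which 20932 carried a gene symbol and gave 15924 genes. Signal levels and detection calls were not among the values, so the precision rested on the number of arrays, and no gene could be placed above or below background. Gene values below are log2 differences ± SE with Benjamini-Hochberg adjusted p from limma.

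Spike-in and negative control spots, which hold no rat sequence, were put through the same fits as the genes. Against the vehicle over the 5 days, 74 of the 108 tests of these 27 spots in 4 materials passed at 0.5 mg/kg, 69 at 1.0 mg/kg and 0 at 2.0 mg/kg (limma, 79, 70 and 11 at an unadjusted p under 0.05). Of these 11, 4 were for CNF1 and 7 for CNF2. The median size of the spot differences at 2.0 mg/kg was 0.08, 0.4, 0.24 and 0.05 for CNF1, CNF2, CNF3 and MWCNT. For CNF2 it was 0.47 at 0.5 mg/kg, so a shift in the CNF2 arrays of 2.0 mg/kg was not excluded. Between vehicles 0 of the adjusted and 9 of the unadjusted tests passed, and at an unadjusted p under 0.05 only 1 test passed in the dose responses and 0 between materials, fewer than chance gives on average, so the spots could not show whether these tests were clear of a shift. The median over all rat probes was 0.096 ± 0.03 (SD, n = 20 arrays) at 0.5 mg/kg and 0.024 ± 0.094 at 1.0 mg/kg, against -0.05 ± 0.042 in the vehicle arrays and -0.063 ± 0.066 at 2.0 mg/kg. The leading principal component held 33.6% of the variance between arrays, and 3 factors computed from these spots accounted for 95.1% of it. The effects of 0.5 and 1.0 mg/kg are therefore given briefly.

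**Figure D1:**
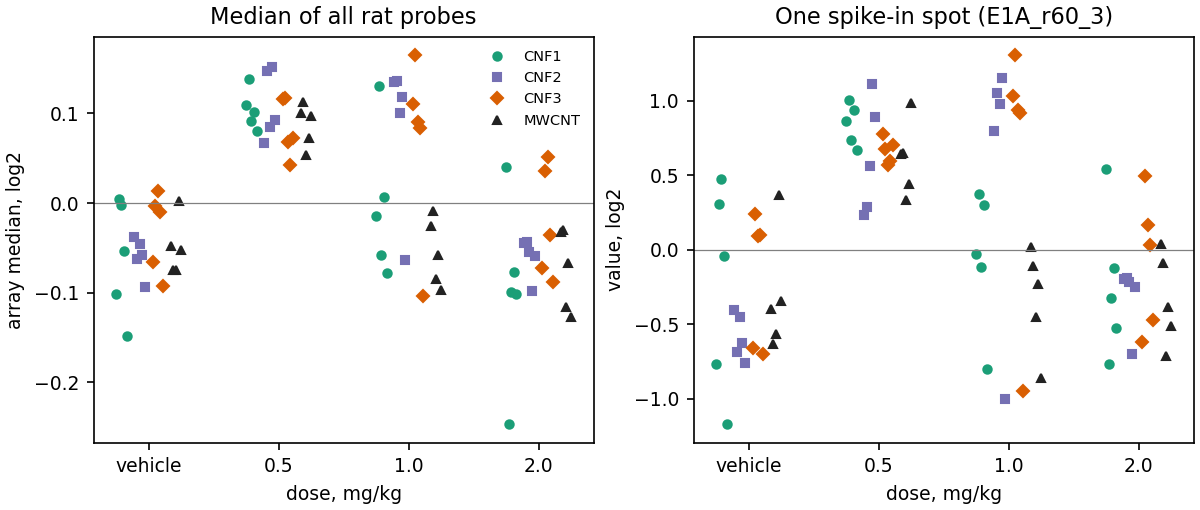
Median log2 value of all rat probes on each of the 80 arrays (left) and the log2 value of 1 spike-in spot (right) by dose, with materials as colours and each point 1 array. Arrays of the 0.5 mg/kg groups lay between 0.043 and 0.152 in the left panel, vehicle arrays between -0.148 and 0.014.

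The effect of each material at 2.0 mg/kg was taken over the 5 days against its own vehicle. After CNF1, Spp1 (osteopontin, a glycoprotein secreted by activated macrophages) rose by 6.45 ± 0.48 and Mmp12 (macrophage metalloelastase) by 6.07 ± 0.53. Mmp7, the matrix protease matrilysin, rose by 5.89 ± 0.62, the dicarboxylate transporter gene Slc13a3 by 4.69 ± 0.45, Ctsk, which encodes the protease cathepsin K, by 4.46 ± 0.39, and Slc26a4, the anion exchanger pendrin, by 4.35 ± 0.39 (largest adjusted p of these 6 genes, 4.6e-10). The largest falls that held on all 5 days were in Ervfrd-1, an endogenous retroviral envelope gene (-2.8 ± 0.5), the olfactory receptor gene Or1e27b (-2.5 ± 0.63), the bitter taste receptor gene Tas2r118 (-2.39 ± 0.41) and Cimap1c (-2.27 ± 0.53), with adjusted p of at most 0.0012. Of the phagocyte activation and particle clearance list, 14 rose, 0 fell and 2 of 16 did not pass (15 up and 0 down adjusted over the list alone). The median was 1.58, with a camera adjusted p = 8.1e-12 and adjusted p = 0.35 with an estimated correlation, and Lgals3 (galectin 3), after Spp1, Ctsk and Mmp12 the member with the smallest p, rose by 1.52 ± 0.15. In the lysosome list 10 rose, 0 fell and 6 of 16 did not pass (10 up and 0 down adjusted over the list alone). Its median stood at 0.64, with a camera adjusted p = 0.00018 and adjusted p = 0.6 with an estimated correlation, and Ctsb (cathepsin B) rose by 0.93 ± 0.11 and Psap (prosaposin) by 0.97 ± 0.14. For the markers of macrophages and monocytes 7 rose, 3 fell and 4 of 14 did not pass (7 up and 3 down adjusted over the list alone). The list median was 0.58, with a camera adjusted p = 0.064 and adjusted p = 0.65 with an estimated correlation; in whole lung more such cells and more RNA per cell look the same. Among monocyte-attracting CC chemokines 7 rose, 1 fell and 1 of 9 did not pass (7 up and 1 down adjusted over the list alone). The median member moved by 1.73 (camera adjusted p = 0.0042, 0.47 with an estimated correlation). Ccl9 stood at 3.18 ± 0.34 and Ccl3 at 1.73 ± 0.23. Cell cycle genes moved up: 13 rose, 0 fell and 7 of 20 did not pass (14 up and 0 down adjusted over the list alone). The median was 0.67 (camera adjusted p = 8e-04, 0.68 with an estimated correlation). Birc5 (survivin) stood at 1.17 ± 0.24. Markers of the alveolar type 1 epithelium, the thin gas-exchange cells, fell: 0 rose, 8 fell and 0 of 8 did not pass (0 up and 8 down adjusted over the list alone). The median came to -0.41 (camera adjusted p = 0.00021, 0.49 with an estimated correlation). Aqp5 stood at -0.72 ± 0.1 and Ager at -0.61 ± 0.1. Of the endothelial markers 0 rose, 8 fell and 4 of 12 did not pass (1 up and 8 down adjusted over the list alone). The middle value was -0.48 (camera adjusted p = 0.0012, 0.49 with an estimated correlation). Eng (endoglin) stood at -1 ± 0.12. Of natural killer and cytotoxic cell markers 0 rose, 7 fell and 3 of 10 did not pass (0 up and 7 down adjusted over the list alone). Members had a median of -0.53 (camera adjusted p = 0.0042, 0.64 with an estimated correlation). Ncr1 stood at -1.01 ± 0.16. In all, 6631 of 15924 genes passed (3476 higher and 3155 lower), 4264 of them with the exposed array on the same side of its vehicle array on 5 of 5 days. By camera 8 of the 44 lists passed as higher and 4 as lower, and 0 with an estimated correlation. The count was 4035 after quantile normalization and 3994 for CNF1 fitted alone, and the 10 genes named first kept their calls in both.

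After CNF2, Mmp12 rose by 6.19 ± 0.53, Mmp7 by 6.17 ± 0.62, Spp1 by 5.72 ± 0.48 and Slc13a3 by 5.53 ± 0.45. Atp6v0d2, a subunit of the vacuolar proton pump, rose by 4.51 ± 0.5 and Sctr, the secretin receptor, by 4.5 ± 0.48 (largest adjusted p of these 6, 1.9e-09). Falls were largest in Ervfrd-1 (-2.15 ± 0.5, adjusted p = 0.00098), Or1e27b (-2.13 ± 0.63, adjusted p = 0.0078), the olfactory receptor gene Or2y1i (-2.08 ± 0.31, adjusted p = 1.5e-06) and Tas2r118 (-1.97 ± 0.41, adjusted p = 3e-04). In the phagocyte activation list 14 rose, 0 fell and 2 of 16 did not pass (15 up and 0 down adjusted over the list alone). This list had a median of 1.55 (camera adjusted p = 1.4e-15, 0.22 with an estimated correlation). Ctsk stood at 4.48 ± 0.39 and Gpnmb, a glycoprotein of lipid-laden macrophages, at 2.49 ± 0.27. In the lysosome list 11 rose, 0 fell and 5 of 16 did not pass (11 up and 0 down adjusted over the list alone). The list moved by a median of 0.53 (camera adjusted p = 1.2e-05, 0.52 with an estimated correlation). Ctsb stood at 0.79 ± 0.11. Of the macrophage and monocyte markers 8 rose, 0 fell and 6 of 14 did not pass (9 up and 1 down adjusted over the list alone). The median was 0.66 (camera adjusted p = 0.0021, 0.49 with an estimated correlation). Of the CC chemokines 6 rose, 0 fell and 3 of 9 did not pass (6 up and 1 down adjusted over the list alone). Its median stood at 1.66 (camera adjusted p = 0.00017, 0.35 with an estimated correlation). Ccl9 stood at 3.43 ± 0.34 and Ccl2, which recruits monocytes, at 2.58 ± 0.34. Among alarmins and type 2 cytokine genes 8 rose, 1 fell and 3 of 12 did not pass (10 up and 2 down adjusted over the list alone). The list median was 1.1, with a camera adjusted p = 0.0016 and adjusted p = 0.4 with an estimated correlation, with the interleukin 33 receptor gene Il1rl1 at 1.32 ± 0.21 and arginase 1 (Arg1) at 1.52 ± 0.24. Ciliated epithelium markers moved down: 0 rose, 7 fell and 5 of 12 did not pass (0 up and 7 down adjusted over the list alone). The median member moved by -0.33 (camera adjusted p = 0.0021, 0.56 with an estimated correlation). Tppp3 stood at -0.49 ± 0.09 and Dnai1, a dynein of motile cilia, at -0.55 ± 0.13. Of the glucocorticoid targets 0 rose, 6 fell and 4 of 10 did not pass (1 up and 6 down adjusted over the list alone). The median was -0.49 (camera adjusted p = 0.023, 0.63 with an estimated correlation). Klf9 stood at -0.6 ± 0.12 and Zbtb16 at -1.21 ± 0.24. Cardiac muscle markers, which in rodents are also made in the walls of the pulmonary veins, were lower: 0 rose, 6 fell and 6 of 12 did not pass (0 up and 6 down adjusted over the list alone). The median came to -0.42 (camera adjusted p = 0.023, 0.68 with an estimated correlation). Sln (sarcolipin) stood at -0.55 ± 0.14. At this dose 4982 of 15924 genes passed (2483 higher and 2499 lower), 3665 of them with the exposed array on the same side of its vehicle array on 5 of 5 days. By camera 11 of the 44 lists passed as higher and 5 as lower, and 0 with an estimated correlation. Without day 3 the count was 2762, and the call of Or1e27b ended without day 3 and with 4 factors of the control spots.

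After CNF3, Spp1 rose by 6.04 ± 0.48, Mmp12 by 5.95 ± 0.53, Slc13a3 by 5.15 ± 0.45 and Mmp7 by 4.84 ± 0.62. Mt3, a metallothionein that binds zinc and copper, rose by 4.4 ± 0.78 and Ctsk by 4.12 ± 0.39 (largest adjusted p of these 6, 6.3e-05). Among the falls were Or1e27b (-1.77 ± 0.63, adjusted p = 0.04), Ervfrd-1 (-1.56 ± 0.5, adjusted p = 0.022) and the cytochrome P450 genes Cyp4f1 (-1.54 ± 0.43, adjusted p = 0.0088) and Cyp2a3 (-1.52 ± 0.35, adjusted p = 0.0014). Of the phagocyte activation genes 14 rose, 0 fell and 2 of 16 did not pass (14 up and 0 down adjusted over the list alone). The middle value was 1.42 (camera adjusted p = 1.4e-20, 0.22 with an estimated correlation). Gpnmb stood at 2.56 ± 0.27. In the lysosome list 10 rose, 0 fell and 6 of 16 did not pass (11 up and 0 down adjusted over the list alone). Members had a median of 0.54 (camera adjusted p = 1.6e-06, 0.49 with an estimated correlation). Ctsb stood at 0.74 ± 0.11. Among macrophage and monocyte markers 6 rose, 0 fell and 8 of 14 did not pass (6 up and 0 down adjusted over the list alone). This list had a median of 0.56 (camera adjusted p = 6e-04, 0.44 with an estimated correlation). Of the metallothioneins and metal handling genes 6 rose, 0 fell and 4 of 10 did not pass (7 up and 0 down adjusted over the list alone). The list moved by a median of 0.44 (camera adjusted p = 8e-04, 0.22 with an estimated correlation). Mt2A stood at 0.85 ± 0.16 and the ferritin light chain gene Ftl1 at 0.61 ± 0.13. Glucocorticoid targets rose here: 5 rose, 0 fell and 5 of 10 did not pass (9 up and 0 down adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.00021, 0.44 with an estimated correlation). Fkbp5 stood at 1.27 ± 0.19 and Cdkn1a at 0.77 ± 0.12. B cell and plasma cell markers fell: 0 rose, 5 fell and 5 of 10 did not pass (0 up and 5 down adjusted over the list alone). Its median stood at -0.27 (camera adjusted p = 0.016, 0.44 with an estimated correlation). Cd79b, a chain of the B cell receptor complex, stood at -0.65 ± 0.11. For CNF3 at 2.0 mg/kg 3143 of 15924 genes passed (1552 higher and 1591 lower), 2816 of them with the exposed array on the same side of its vehicle array on 5 of 5 days. By camera 11 of the 44 lists passed as higher and 5 as lower, and 0 with an estimated correlation. The count was 1452 without day 1, 1685 without day 7, 1963 without day 30, 4754 after quantile normalization, 5064 with a common control of the 4 vehicles and 1402 without the 0.5 and 1.0 mg/kg arrays. The call of Or1e27b ended with either set of control-spot factors and without day 1, 3, 7 or 30, that of Ervfrd-1 with 4 factors and without day 7 or 30, and that of Cyp4f1 without day 1 or 7; those of Or1e27b, Ervfrd-1 and Cyp2a3 ended without the 0.5 and 1.0 mg/kg arrays.

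After MWCNT, Spp1 rose by 5.84 ± 0.48, Slc26a4 by 4.63 ± 0.39, Mmp12 by 4.6 ± 0.53 and Mmp7 by 4.01 ± 0.62. Mab21l3 rose by 3.83 ± 0.44 and Lcn2, the iron-binding defence protein lipocalin 2, by 3.61 ± 0.54 (largest adjusted p of these 6, 5.8e-06). The falls were led by Or1e27b (-1.89 ± 0.63, adjusted p = 0.025), the neuropeptide gene Cartpt (-1.58 ± 0.49, adjusted p = 0.016), the olfactory receptor gene Or5h18 (-1.51 ± 0.56, adjusted p = 0.045) and Tac1, the precursor of substance P (-1.48 ± 0.31, adjusted p = 0.00049). In the phagocyte activation list 14 rose, 0 fell and 2 of 16 did not pass (15 up and 0 down adjusted over the list alone). The list median was 1.25, with a camera adjusted p = 4.6e-16 and adjusted p = 0.22 with an estimated correlation, with the scavenger receptor gene Msr1 at 1.21 ± 0.15. In the macrophage and monocyte markers 8 rose, 0 fell and 6 of 14 did not pass (8 up and 0 down adjusted over the list alone). The median member moved by 0.69 (camera adjusted p = 0.00047, 0.44 with an estimated correlation). All measured neutrophil-attracting CXC chemokines rose: 4 rose, 0 fell and 0 of 4 did not pass (4 up and 0 down adjusted over the list alone). The median was 1.45 (camera adjusted p = 0.00013, 0.22 with an estimated correlation). Cxcl6 stood at 2.31 ± 0.36 and Cxcl2 at 2.09 ± 0.31. Of the neutrophil markers 6 rose, 1 fell and 9 of 16 did not pass (6 up and 1 down adjusted over the list alone). The median came to 0.38 (camera adjusted p = 0.0093, 0.49 with an estimated correlation). Cd177 stood at 3.51 ± 0.32 and S100a9, a subunit of calprotectin, at 1.85 ± 0.27. Interferon response genes rose: 11 rose, 0 fell and 5 of 16 did not pass (12 up and 0 down adjusted over the list alone). The middle value was 0.72 (camera adjusted p = 1.6e-06, 0.49 with an estimated correlation). Cxcl11 stood at 2.54 ± 0.42, Cxcl10 at 2.2 ± 0.39 and Ifit3 at 1.3 ± 0.24. Of the acute phase and secreted defence genes 8 rose, 0 fell and 5 of 13 did not pass (8 up and 0 down adjusted over the list alone). Members had a median of 0.68 (camera adjusted p = 4.9e-05, 0.22 with an estimated correlation). C3 stood at 1.86 ± 0.23 and haptoglobin (Hp) at 1.08 ± 0.17. In cholesterol synthesis 7 rose, 0 fell and 2 of 9 did not pass (8 up and 0 down adjusted over the list alone). This list had a median of 0.65 (camera adjusted p = 4.8e-06, 0.44 with an estimated correlation). Dhcr7 stood at 0.71 ± 0.12 and Fdps at 0.65 ± 0.11. In the cell cycle list 17 rose, 0 fell and 3 of 20 did not pass (20 up and 0 down adjusted over the list alone). The list moved by a median of 0.96 (camera adjusted p = 2.8e-11, 0.44 with an estimated correlation). Ccna2 (cyclin A2) stood at 1.32 ± 0.25. Of the alveolar type 1 markers 0 rose, 7 fell and 1 of 8 did not pass (0 up and 8 down adjusted over the list alone). The median was -0.29 (camera adjusted p = 0.00034, 0.49 with an estimated correlation). Cav1 (caveolin 1) stood at -0.54 ± 0.11. Across all genes, 3478 of 15924 genes passed (2022 higher and 1456 lower), 3149 of them with the exposed array on the same side of its vehicle array on 5 of 5 days. By camera 18 of the 44 lists passed as higher and 4 as lower, and 0 with an estimated correlation. The count was 2120 without day 7, 2236 without day 30, 5354 with a common control of the 4 vehicles and 1866 without the 0.5 and 1.0 mg/kg arrays. The call of Or5h18 ended in each fit that left out a day, with either set of control-spot factors, with a common control of the 4 vehicles and after quantile normalization, that of Cartpt without day 1 or day 90 and with the common control, and that of Or1e27b without day 1, day 3 or day 90.

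**Figure D2:**
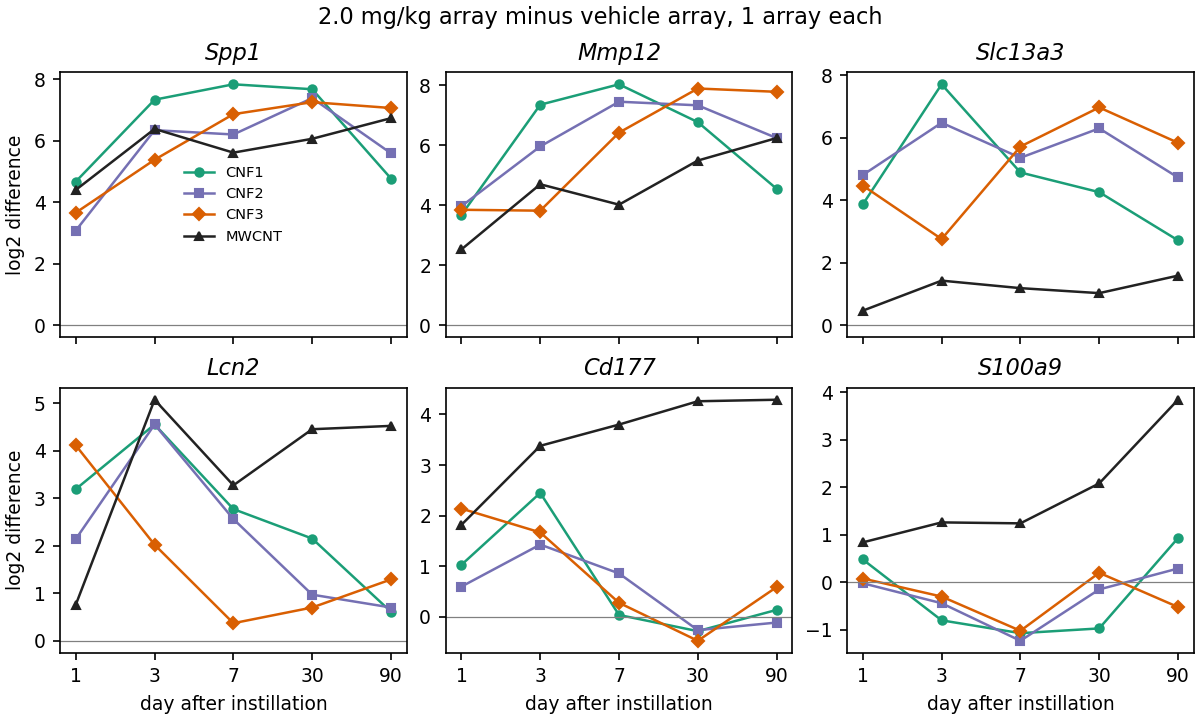
Log2 difference between the 2.0 mg/kg array and the vehicle array (y axis) on each day after instillation (x axis) for 6 genes, with 1 array per point and materials as colours. Spp1 lay above its vehicle in every material on every day, and Cd177 after MWCNT went from 1.82 on day 1 to 4.29 on day 90.

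**Figure D3:**
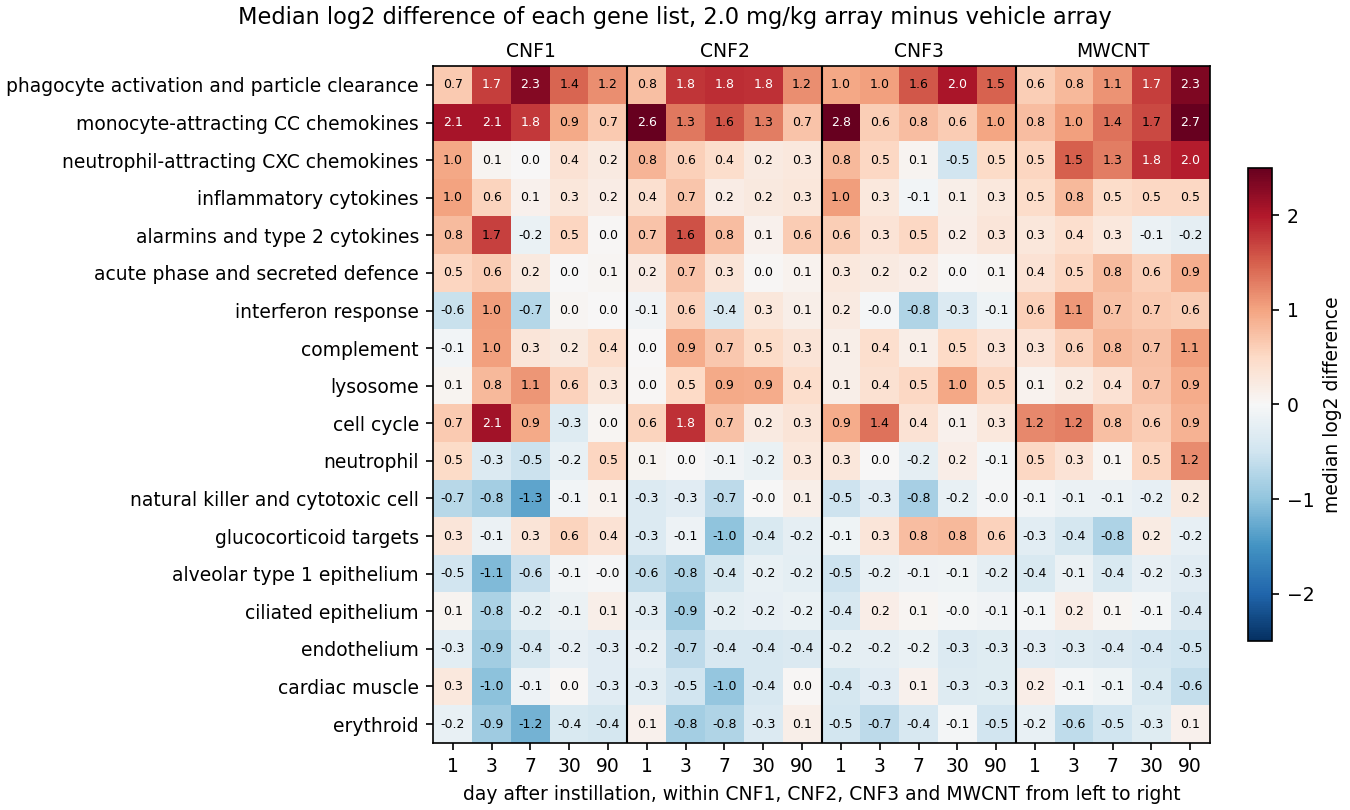
Median log2 difference of the members of 18 gene lists between the 2.0 mg/kg array and the vehicle array, by day, with each square coloured and labelled by its value and 1 array on each side. The cell cycle median was 2.09 on day 3 after CNF1, where the reference gene median was 0.65. The interferon response median after MWCNT was 0.59, 1.09, 0.74, 0.65 and 0.61 on days 1, 3, 7, 30 and 90.

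At the lower doses Spp1 was also higher, by 3.69 ± 0.48 after CNF1, 3.74 ± 0.48 after CNF2, 3.72 ± 0.48 after CNF3 and 2.76 ± 0.48 after MWCNT at 0.5 mg/kg, and by 5.01 ± 0.48, 5.06 ± 0.48, 5.19 ± 0.48 and 3.89 ± 0.48 at 1.0 mg/kg (largest adjusted p, 2e-05). Mmp12 after 0.5 mg/kg was higher by 3.66 ± 0.53, 3.99 ± 0.53, 4.34 ± 0.53 and 2.41 ± 0.53 in the same order of materials (largest adjusted p, 0.00041). With 3 factors of the control spots the Spp1 calls ended for CNF1 (3.31 ± 1.01, adjusted p = 0.053) and MWCNT (2.38 ± 0.96, 0.18) at 0.5 mg/kg and for MWCNT at 1.0 mg/kg (3.32 ± 0.8, 0.12). The Mmp12 calls ended for CNF1 (3.4 ± 1.05, 0.058) and MWCNT (2.13 ± 1, 0.25). With 4 factors of all control spots only the Spp1 call of CNF3 at 1.0 mg/kg (adjusted p = 3.3e-05) was left of all these, but Spp1 at 0.5 mg/kg still stood at 3.71 ± 1.27, 4.02 ± 1.28, 3.93 ± 1.1 and 2.75 ± 1.19 and Mmp12 at 3.68 ± 1.34, 4.39 ± 1.34, 4.56 ± 1.16 and 2.38 ± 1.25, so precision was lost and not the size of the rise. At 0.5 mg/kg 7558, 8054, 4675 and 6028 genes passed, 5745 and 1813 higher and lower after CNF1, 6004 and 2050 after CNF2, 3793 and 882 after CNF3 and 4843 and 1185 after MWCNT. Quantile normalization turned these splits to 3218 and 4630, 3212 and 5504, 2465 and 4250 and 2870 and 3924, and the CNF3 count was 2046 without day 1. At 1.0 mg/kg 5863, 6356, 3949 and 2547 genes passed, with 3287 and 2576, 4397 and 1959, 2979 and 970 and 1347 and 1200 higher and lower, against 2267 and 2992 for CNF1, 2545 and 5811 for CNF2, 1898 and 4204 for CNF3 and 2532 and 1875 for MWCNT after quantile normalization. Fitted alone CNF1 gave 4830 genes at 0.5 mg/kg and 2082 at 1.0 mg/kg, and MWCNT 4004 at 1.0 mg/kg. With 3 control-spot factors the counts were 535, 1884, 2899 and 236 at 0.5 mg/kg and 490, 131, 1092 and 0 at 1.0 mg/kg, and with 4 factors 2, 0, 10 and 3 at 0.5 mg/kg and 0, 3, 337 and 0 at 1.0 mg/kg. Single days weighed on the counts at 1.0 mg/kg: without day 3 the CNF1 count was 3133, CNF3 gave 1633, 1979 and 2246 without days 1, 3 and 30, and MWCNT 1252, 1240 and 735 without days 1, 7 and 30. The median over all genes moved with quantile normalization from 0.134 to -0.073 in CNF1, 0.139 to -0.098 in CNF2, 0.107 to -0.054 in CNF3 and 0.127 to -0.051 in MWCNT at 0.5 mg/kg, and from 0.078 to -0.128 in CNF2 and 0.066 to -0.085 in CNF3 at 1.0 mg/kg, so a direction at these doses was relative to that choice.

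The dose response on each day was a slope over the vehicle and the 3 doses, in log2 per mg/kg, and asked which genes rose or fell with dose. With CNF1 day 3 had the highest count, when Mmp7 (3.9 ± 1.2), Slc13a3 (3.72 ± 0.73) and Mmp12 (3.32 ± 1.07) rose with dose. Ervfrd-1 (-2.79 ± 0.82) and Tas2r118 (-2.47 ± 0.74) fell (largest adjusted p, 0.017). That day 16 cell cycle genes rose, 0 fell and 4 of 20 did not pass (19 up and 0 down adjusted over the list alone). The median was 0.98 (camera adjusted p = 9.2e-10, 0.24 with an estimated correlation). Birc5 stood at 1.47 ± 0.18 and the cyclin gene Ccnb1 at 1.29 ± 0.19. On day 1 the cytokine gene Il24 (2.68 ± 0.58), Calcb, a calcitonin gene-related peptide (1.71 ± 0.47), and Mro (1.59 ± 0.4) rose. The methyltransferase gene Inmt (-1.5 ± 0.41) and Rnase17 (-1.32 ± 0.39) fell (largest adjusted p, 0.035). On day 7 Spp1 (3.86 ± 0.97), Mmp12 (3.75 ± 1.07) and Ctsk (2.89 ± 0.67) rose. Fpr3, a formyl peptide receptor (-1.53 ± 0.3), and Cyp4f1 (-1.41 ± 0.4) fell (largest adjusted p, 0.027). On day 7, 13 phagocyte activation genes rose, 0 fell and 3 of 16 did not pass (15 up and 0 down adjusted over the list alone). The list median was 1.19 (camera adjusted p = 4.5e-18, 0.041 with an estimated correlation). Of the lysosome genes 10 rose, 0 fell and 6 of 16 did not pass (11 up and 0 down adjusted over the list alone). The median member moved by 0.57 (camera adjusted p = 5e-14, 0.019 with an estimated correlation). On day 30 Mt3 (3.03 ± 0.61), the fatty acid binding protein gene Fabp4 (1.44 ± 0.27) and the cystatin gene Cst6 (1.32 ± 0.29) rose. The airway secretory genes Bpifa1 (-1.61 ± 0.34) and Scgb3a1 (-1.11 ± 0.24) fell (largest adjusted p, 0.043). Of the club and goblet genes 0 rose, 2 fell and 11 of 13 did not pass (0 up and 3 down adjusted over the list alone). The median was -0.26 (camera adjusted p = 0.00041, 0.036 with an estimated correlation). On day 90 Eral1 (0.67 ± 0.12) and the metalloprotease gene Adamts9 (0.52 ± 0.09) passed, both with adjusted p = 0.019. The counts were 999, 4437, 992, 20 and 2 on days 1, 3, 7, 30 and 90, of which 424, 2460, 531, 13 and 2 rose. Without 0.5 mg/kg 831, 4025, 624, 6 and 0 genes passed and without 1.0 mg/kg 646, 3846, 645, 1 and 0. Without 2.0 mg/kg 65, 2331, 154, 1 and 0 passed, day 3 still leading. The day 3 array of that dose had the lowest median (-0.247) and largest SD (0.776) of all arrays. The reference gene median rose by 0.65 on it. With 3 control-spot factors the counts were 327, 5960, 2152, 160 and 15, and on day 1 Calcb (1.52 ± 0.43, adjusted p = 0.053) and Rnase17 (-1.52 ± 0.44, adjusted p = 0.054) lost their calls at slopes about as large as before; the spike-in and negative spots had a median slope size of 0.64 on that day. Fitted without the other materials 3, 2666, 123, 1 and 0 genes passed, and of the named genes those of day 3, Fpr3 and Mt3 kept their calls, while only Il24, Mro, Slc13a3 and Ctsk did whichever dose was left out. The mean of the 3 exposed arrays gave 376, 2700, 60, 4 and 1 genes and kept the calls of Il24, Calcb and Mro, of Mmp7, Slc13a3 and Mmp12 on day 3 and of Mmp12 and Ctsk on day 7, and a common control gave 3510, 6671, 3423, 412 and 1. After quantile normalization 0, 565, 277, 10 and 0 passed, with splits of 549 up and 16 down on day 3 (2460 and 1977 before), 269 and 8 on day 7 (531 and 461) and 9 and 1 on day 30 (13 and 7), and the median slope over all genes on day 3 moved from -0.086 to 0.062. The named genes that kept their calls were Slc13a3 on day 3, Spp1 and Ctsk on day 7 and Mt3 on day 30.

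**Figure D4:**
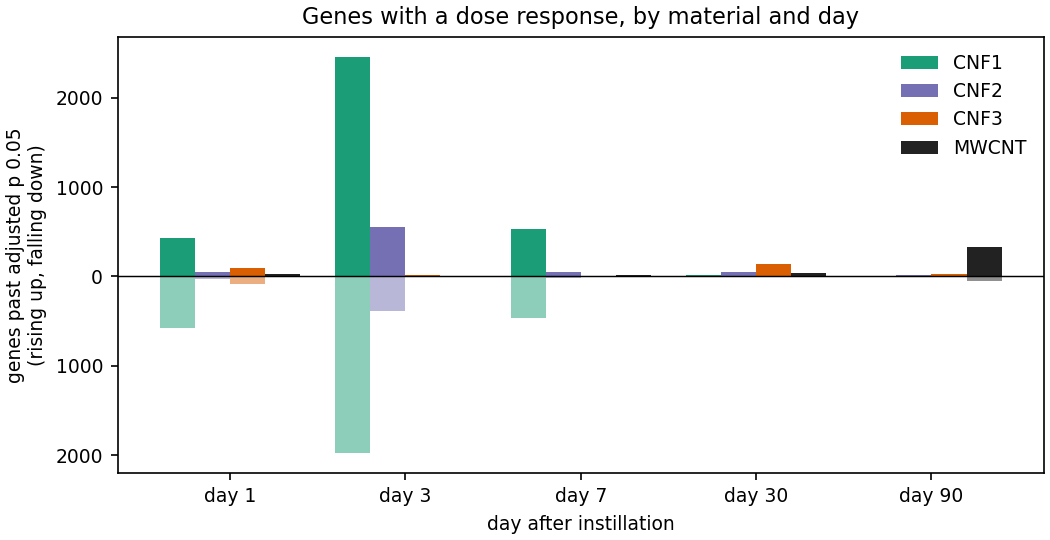
Number of genes whose dose response passed an adjusted p of 0.05 (y axis; rising genes above 0, falling genes in lighter bars below) by day after instillation and material. The bars reach 2460 up and 1977 down for CNF1 on day 3, and 330 up and 57 down for MWCNT on day 90.

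With CNF2, too, day 3 had the highest count, when Slc13a3 (2.82 ± 0.73), Acod1, which makes itaconate in activated macrophages (2.74 ± 0.76), and Tmem213 (2.64 ± 0.63) rose. The bile acid conjugating enzyme gene Baat (-1.4 ± 0.35) and Tac1 (-1.36 ± 0.34) fell (largest adjusted p, 0.025). Cell cycle genes rose with dose on day 3: 9 rose, 0 fell and 11 of 20 did not pass (18 up and 0 down adjusted over the list alone). The median came to 0.78 (camera adjusted p = 8.4e-13, 0.17 with an estimated correlation). Birc5 stood at 0.97 ± 0.18. Of the ciliated epithelium genes 0 rose, 7 fell and 5 of 12 did not pass (0 up and 7 down adjusted over the list alone). The middle value was -0.37 (camera adjusted p = 3.6e-07, 0.062 with an estimated correlation). On day 1 Il1rn, the interleukin 1 receptor antagonist (1.43 ± 0.34), Inhba, a subunit of activin A (1.23 ± 0.28), and the transcription factor gene Fosl1 (1.18 ± 0.28) rose. Cyp2a3 (-1.53 ± 0.27) and Rnase10 (-1.25 ± 0.28) fell (largest adjusted p, 0.033). Immediate early genes, which respond within minutes to stimulation, rose with dose on day 1: 3 rose, 0 fell and 10 of 13 did not pass (5 up and 0 down adjusted over the list alone). Members had a median of 0.3, with a camera adjusted p = 5.5e-09 and adjusted p = 0.013 with an estimated correlation. Egr2 stood at 1.16 ± 0.23. On day 7 the neuropeptide gene Trh (2.17 ± 0.47), the serine protease gene Prss22 (1.47 ± 0.21) and Dcstamp, needed for macrophage fusion (1.33 ± 0.25), rose. Cyp4f4 (-1.04 ± 0.25) and Scgb3a1 (-1.01 ± 0.24) fell (largest adjusted p, 0.042). Of the glucocorticoid targets 0 rose, 1 fell and 9 of 10 did not pass (0 up and 6 down adjusted over the list alone). This list had a median of -0.44, with a camera adjusted p = 1.8e-08 and adjusted p = 0.041 with an estimated correlation. On day 30 Mt3 (3.19 ± 0.61), the melanosome gene Mlana (2.73 ± 0.46) and Atp6v0d2 (2.51 ± 0.61) rose. The acyltransferase gene Mboat2 (-0.38 ± 0.09) fell. On day 90 Mt3 (3.12 ± 0.61), Mlana (2.38 ± 0.46) and Fabp4 (1.26 ± 0.27) rose (largest adjusted p, 0.049 and 0.045). On day 30 phagocyte activation genes rose with dose: 3 rose, 0 fell and 13 of 16 did not pass (13 up and 0 down adjusted over the list alone). The list moved by a median of 0.86, with a camera adjusted p = 2.4e-31 and adjusted p = 0.0084 with an estimated correlation. Of the lysosome genes 3 rose, 0 fell and 13 of 16 did not pass (10 up and 0 down adjusted over the list alone). The median was 0.42, with a camera adjusted p = 5.9e-23 and adjusted p = 0.003 with an estimated correlation. The counts were 77, 941, 67, 53 and 10, with 44, 548, 52, 52 and 10 rising. With the 0.5 mg/kg arrays left out, 166, 2240, 145, 35 and 1 genes passed, without 1.0 mg/kg 23, 542, 13, 12 and 5, and without 2.0 mg/kg 58, 3, 2, 1 and 0. CNF2 fitted alone gave 1, 8, 1, 6 and 0, with calls kept by Dcstamp on day 7 and Mt3 and Mlana on day 30, and with 3 control-spot factors 212, 1662, 336, 235 and 90 passed. Only Prss22 kept its call whichever dose was left out. The mean of the 3 exposed arrays gave 116, 1878, 163, 11 and 0 and kept the calls of Rnase10, of the 5 genes of day 3 and of Scgb3a1, and a common control gave 2180, 4822, 1605, 451 and 171. After quantile normalization 0, 0, 10, 68 and 0 passed, with 10 up and 0 down on day 7 against 52 and 15 before, and the named genes that kept their calls were Trh, Prss22 and Dcstamp on day 7 and Mt3 and Mlana on day 30.

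With CNF3, on day 1 Il24 (2.68 ± 0.58), the acute phase gene Orm1 (2.53 ± 0.54) and Calcb (1.97 ± 0.47) rose. The neuronal pentraxin gene Nptx1 (-1.73 ± 0.21) and Cyp4f1 (-1.63 ± 0.4) fell (largest adjusted p, 0.031). Immediate early genes rose on day 1: 3 rose, 0 fell and 10 of 13 did not pass (6 up and 0 down adjusted over the list alone). Its median stood at 0.53 (camera adjusted p = 8.5e-08, 0.019 with an estimated correlation). Ier3 stood at 0.62 ± 0.09 and Fos at 0.78 ± 0.15. On day 3 Upk3bl1 (1.69 ± 0.26), the phospholipase gene Pla2g10 (1.28 ± 0.2) and the water channel gene Aqp3 (1.28 ± 0.28) rose. Lhpp (-1.66 ± 0.17) and the cardiac kinase gene Mylk3 (-0.48 ± 0.1) fell. On day 7 Dcstamp (1.31 ± 0.25), Prss30 (1.26 ± 0.21) and Qprt (0.72 ± 0.14) rose (largest adjusted p, 0.046 and 0.019). On day 30 Mt3 (3.5 ± 0.61), Slc13a3 (3.03 ± 0.73) and the apolipoprotein gene Apoa4 (2.96 ± 0.48) rose. Sfrp2, a Wnt antagonist (-0.66 ± 0.17), and Nostrin (-0.57 ± 0.14) fell (largest adjusted p, 0.045). The phagocyte activation list rose with dose on day 30: 7 rose, 0 fell and 9 of 16 did not pass (15 up and 0 down adjusted over the list alone). The list median was 0.93 (camera adjusted p = 7.6e-30, 0.0084 with an estimated correlation). Of the lysosome genes 5 rose, 0 fell and 11 of 16 did not pass (11 up and 0 down adjusted over the list alone). The median member moved by 0.45 (camera adjusted p = 2.6e-22, 0.003 with an estimated correlation). Glucocorticoid targets rose on day 30 as a list: 0 rose, 0 fell and 10 of 10 did not pass (8 up and 0 down adjusted over the list alone). The median was 0.38 (camera adjusted p = 1.1e-09, 0.033 with an estimated correlation). On day 90 Mt3 (3.15 ± 0.61), Mlana (2.77 ± 0.46) and the potassium channel gene Kcnv1 (2.28 ± 0.44) rose (largest adjusted p, 0.0082). The counts were 179, 17, 5, 142 and 22, with 96, 15, 5, 137 and 22 rising. Leaving out the 0.5 mg/kg arrays gave 231, 7, 5, 136 and 16, the 1.0 mg/kg arrays 63, 5, 0, 68 and 13 and the 2.0 mg/kg arrays 3, 8, 0, 27 and 6. CNF3 fitted alone gave 70, 1, 0, 30 and 5, with calls kept by Orm1 and Nptx1 on day 1 and Kcnv1 on day 90, and with 3 control-spot factors 681, 116, 60, 361 and 120 passed. Only Mt3 and Apoa4 on day 30 kept their calls whichever dose was left out. The mean of the 3 exposed arrays gave 101, 4, 0, 11 and 1 and kept the calls of these 2 and of Il24, Orm1 and Calcb, and a common control gave 1366, 361, 258, 686 and 296. After quantile normalization 2, 12, 8, 208 and 3 passed, with 5 up and 7 down on day 3 against 15 and 2 before, and the calls kept were those of Nptx1 on day 1, Upk3bl1, Pla2g10 and Lhpp on day 3, Dcstamp and Prss30 on day 7 and Mt3 on day 30.

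With MWCNT the highest count was that of day 90, when Slc26a4 (2.97 ± 0.79), the peroxidase gene Lpo (2.49 ± 0.6) and Mab21l3 (2.43 ± 0.67) rose. The interferon gene Ifna5 (-1.23 ± 0.3) and the olfactory receptor gene Or12j2 (-1.09 ± 0.25) fell (largest adjusted p, 0.037). On that day phagocyte activation genes rose with dose: 8 rose, 0 fell and 8 of 16 did not pass (16 up and 0 down adjusted over the list alone). The median came to 1.22 (camera adjusted p = 1.2e-21, 0.027 with an estimated correlation). Of the lysosome genes 9 rose, 0 fell and 7 of 16 did not pass (13 up and 0 down adjusted over the list alone). The middle value was 0.49 (camera adjusted p = 1e-17, 0.0084 with an estimated correlation). Of the complement genes 5 rose, 0 fell and 8 of 13 did not pass (8 up and 0 down adjusted over the list alone). Members had a median of 0.52 (camera adjusted p = 1.6e-11, 0.042 with an estimated correlation). Cfb (factor B) stood at 0.74 ± 0.1. Neutrophil markers rose too: 5 rose, 0 fell and 11 of 16 did not pass (8 up and 1 down adjusted over the list alone). This list had a median of 0.57 (camera adjusted p = 3.1e-06, 0.17 with an estimated correlation). S100a9 stood at 1.94 ± 0.22 and S100a8, the other subunit of calprotectin, at 1.16 ± 0.23. On day 1 Il24 (2.85 ± 0.58), Wfdc18 (2.05 ± 0.42) and Fosl1 (1.42 ± 0.28) rose. Tnfrsf8, the receptor CD30 (-0.85 ± 0.16), and the histone deacetylase gene Hdac11 (-0.51 ± 0.1) fell (largest adjusted p, 0.018). On day 3 limma called 0 genes, and 668 had an unadjusted p under 0.05. On day 7 Upk3bl1 (1.18 ± 0.26), Prss30 (0.97 ± 0.21) and Sectm1a (0.96 ± 0.21) rose. Vof16 (-0.79 ± 0.18) and Rflnb (-0.59 ± 0.09) fell. On day 30 Gpr25 (1.83 ± 0.37), the dermokine gene Dmkn (1.81 ± 0.39) and Fabp4 (1.47 ± 0.27) rose. Tpd52l1 (-0.84 ± 0.18) fell (largest adjusted p, 0.046 and 0.031). As a list, cholesterol synthesis genes rose with dose on day 7: 0 rose, 0 fell and 9 of 9 did not pass (6 up and 0 down adjusted over the list alone). The list moved by a median of 0.39, with a camera adjusted p = 2.8e-13 and adjusted p = 0.034 with an estimated correlation. The counts were 23, 0, 25, 39 and 387, with 21, 0, 17, 38 and 330 rising. Without 0.5 mg/kg they were 46, 0, 9, 11 and 206, without 1.0 mg/kg 4, 2, 6, 13 and 194 and without 2.0 mg/kg 3, 0, 1, 3 and 9, and the slope of Gpr25 on day 30 was -0.12 without 2.0 mg/kg. MWCNT fitted alone gave 7, 1, 0, 20 and 361, with calls kept by Il24 and Tnfrsf8 on day 1, Fabp4 and Tpd52l1 on day 30 and Mab21l3, Ifna5 and Or12j2 on day 90, while no named gene kept its call whichever dose was left out. With 3 control-spot factors 128, 44, 178, 283 and 893 passed, with 4 factors 239, 49, 352, 465 and 1256, with a common control 701, 131, 716, 726 and 1699, and with the mean of the 3 exposed arrays 18, 14, 6, 3 and 24, where Il24, Wfdc18, Slc26a4 and Mab21l3 kept their calls. After quantile normalization 2, 1, 9, 39 and 81 passed, with 79 up and 2 down on day 90 against 330 and 57 before, and the calls of the named genes of day 1, Rflnb, Tpd52l1, Slc26a4 and Mab21l3 ended.

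Whether a dose response had changed by day 90 was tested as the slope on day 90 minus that on day 1. For MWCNT the slope rose for the mucin gene Muc20 (1.96 ± 0.19, adjusted p = 5e-09), the kininogen genes Kng2 (1.22 ± 0.18) and Kng1 (1.43 ± 0.23), and Cdkn2a, an inhibitor of the cell cycle (1.28 ± 0.21). Gfra3 (0.72 ± 0.13), the amino acid transporter gene Slc7a7 (1.18 ± 0.22), the cytokine gene Il18 (0.8 ± 0.15) and Adig (1.13 ± 0.22) rose too, with adjusted p of at most 0.0095. For CNF3 the slope rose for Qprt (1.28 ± 0.2), Serping1, the inhibitor of complement C1 (0.84 ± 0.14), the protease inhibitor A2m (0.97 ± 0.17), Atp2b2 (1.54 ± 0.29), Ptcd3 (0.73 ± 0.14) and Plppr4 (1.51 ± 0.3), and fell for the cytokine gene Il1b (-1.05 ± 0.22) and Ier3 (-0.59 ± 0.12), with adjusted p of at most 0.04. In all, 26 genes passed for MWCNT (25 up and 1 down) and 14 for CNF3 (10 up and 4 down), and limma called 0 for CNF1 and 0 for CNF2, with 1129 and 503 at an unadjusted p under 0.05. These 16 genes were the 8 with the smallest p of each material, named after their values were seen. Without the 0.5, 1.0 or 2.0 mg/kg arrays CNF1 gave 2, 1 and 2 genes, CNF2 0, 0 and 3, CNF3 10, 2 and 0, and MWCNT 3, 17 and 0. Quantile normalization left 1 gene for MWCNT, Muc20, and 0 for the other materials. Fitted alone CNF3 gave 1 and MWCNT 14, with calls kept by Plppr4 and by Muc20, Cdkn2a and Il18, and the mean of the 3 exposed arrays against the vehicle ended all 16 calls. With 3 control-spot factors the 4 materials gave 0, 32, 32 and 113, with 4 factors 26, 69, 53 and 170 and with a common control 334, 232, 129 and 193 genes.

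The materials were compared by the difference between their 2.0 mg/kg effects over the 5 days. MWCNT against CNF1 gave higher Cd177, a neutrophil surface protein (2.83 ± 0.46), the macrophage complement receptor Vsig4 (2.69 ± 0.72), S100a9 (2.14 ± 0.38) and Rnase9 (2.1 ± 0.53). Lower were Slc13a3 (-3.55 ± 0.64), Zbtb16 (-2.35 ± 0.35) and Ctsk (-2.18 ± 0.54), with adjusted p of at most 0.038. Against CNF2, Cd177 (3.01 ± 0.46), S100a9 (2.16 ± 0.38), the IgA receptor gene Fcar (1.68 ± 0.37) and Noxo1, a subunit of an NADPH oxidase (1.48 ± 0.25), were higher after MWCNT, and Slc13a3 (-4.39 ± 0.64), the GABA receptor gene Gabbr2 (-2.08 ± 0.45) and the transcription factor gene Egr2 (-1.27 ± 0.28) lower, with adjusted p of at most 0.033. Against CNF3, Cd177 (2.67 ± 0.46), Rnase9 (2.5 ± 0.53), S100a9 (2.17 ± 0.38) and Rgs9 (1.85 ± 0.29) were higher, and Slc13a3 (-4.01 ± 0.64), the gelatinase gene Mmp9 (-2.64 ± 0.55) and Cst6 (-2.52 ± 0.62) lower, with adjusted p of at most 0.044. Of the neutrophil-attracting CXC chemokines in MWCNT against CNF3 1 rose, 0 fell and 3 of 4 did not pass (3 up and 0 down adjusted over the list alone). The median was 1.06 (camera adjusted p = 1.6e-06, 0.028 with an estimated correlation). Cxcl1 stood at 1.27 ± 0.28. In the interferon response list for MWCNT against CNF1 2 rose, 0 fell and 14 of 16 did not pass (10 up and 0 down adjusted over the list alone). Its median stood at 0.76, with a camera adjusted p = 6.5e-07 and adjusted p = 0.42 with an estimated correlation. Mx1 stood at 1.45 ± 0.34. Against CNF2, of the same list 0 rose, 0 fell and 16 of 16 did not pass (2 up and 0 down adjusted over the list alone). The list median was 0.54, with a camera adjusted p = 1e-08 and adjusted p = 0.25 with an estimated correlation, and against CNF3 3 rose, 0 fell and 13 of 16 did not pass (15 up and 0 down adjusted over the list alone). The median member moved by 0.89, with a camera adjusted p = 9.1e-18 and adjusted p = 0.057 with an estimated correlation. MWCNT gave 260 called genes against CNF1 (128 and 132 higher and lower), 17 against CNF2 (13 and 4) and 77 against CNF3 (50 and 27). The count against CNF1 was 109 without day 1, 34 without day 7, 19 without day 30 and 668 without day 90, that against CNF2 31 without day 1, 9 without day 3, 7 without day 7, 3 without day 30 and 11 without day 90, and that against CNF3 142 without day 1, 10 without day 7, 13 without day 30 and 23 without day 90. With the 2.0 mg/kg and vehicle arrays alone 1, 0 and 1 genes passed against CNF1, CNF2 and CNF3, and the 7 genes named first in each difference lost their calls. Without day 30 S100a9 lost its call against CNF1 and CNF2, and Cd177 lost its call against CNF3 without day 7 or day 30. Calls that held whichever day was left out were those of Cd177, Slc13a3 and Zbtb16 against CNF1, Cd177 and Slc13a3 against CNF2, and S100a9, Rgs9 and Slc13a3 against CNF3. Quantile normalization gave 22, 9 and 144 (119 higher and 25 lower against CNF3) and ended the calls of Vsig4, Rnase9 and Ctsk against CNF1, Gabbr2 and Egr2 against CNF2 and Cst6 against CNF3. A common control of the 4 vehicles, which cancels out of a difference and leaves any shift between the arrays of 2 materials in it, gave 3815, 791 and 940 and ended the call of Zbtb16 against CNF1 (-0.52).

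Between the cellulose materials, CNF2 against CNF1 had lower Zbtb16 (-2.73 ± 0.35) and Fkbp5 (-1.52 ± 0.26), both induced by glucocorticoids, and Tent5b (-1.34 ± 0.28). Higher were Msx1 (0.75 ± 0.17), Filip1l (0.73 ± 0.14), Lzts1 (0.63 ± 0.14) and Arhgap20 (0.62 ± 0.14), with adjusted p of at most 0.024. CNF3 against CNF2 had higher Zbtb16 (2.14 ± 0.35), Tent5b (1.73 ± 0.28), Klf15, another glucocorticoid-induced factor (1.5 ± 0.28), and Mpp3 (1.42 ± 0.18). Lower were Meox2 (-0.62 ± 0.13), Hhex (-0.5 ± 0.11) and Vgll4 (-0.27 ± 0.06), with adjusted p of at most 0.021. Glucocorticoid targets were lower after CNF2 than after CNF1: 0 rose, 4 fell and 6 of 10 did not pass (0 up and 8 down adjusted over the list alone). At a median of -0.62, there was a camera adjusted p = 6.8e-15 and adjusted p = 0.0082 with an estimated correlation. Per1 stood at -1.23 ± 0.23. They were higher after CNF3 than after CNF2: 5 rose, 0 fell and 5 of 10 did not pass (8 up and 0 down adjusted over the list alone). The median came to 0.84, with a camera adjusted p = 1.2e-26 and adjusted p = 0.00016 with an estimated correlation. Per1 stood at 1.37 ± 0.23 and Klf9 at 0.94 ± 0.17. After MWCNT they were lower than after CNF3: 0 rose, 6 fell and 4 of 10 did not pass (0 up and 8 down adjusted over the list alone). The middle value was -0.79, with a camera adjusted p = 2.5e-17 and adjusted p = 0.0039 with an estimated correlation. Fkbp5 stood at -1.38 ± 0.26. Against CNF1 the same list gave a fall after MWCNT: 0 rose, 5 fell and 5 of 10 did not pass (0 up and 6 down adjusted over the list alone). Members had a median of -0.7, with a camera adjusted p = 5e-07 and adjusted p = 0.14 with an estimated correlation. These differences share arrays, so they are not independent of each other. CNF2 against CNF1 gave 33 called genes (8 and 25 higher and lower), CNF3 against CNF2 24 (21 and 3), and CNF3 against CNF1 0 by limma, with 1265 at an unadjusted p under 0.05. The median SE of a difference was 0.166, and a count of 0 does not show that CNF1 and CNF3 acted alike. The count of CNF2 against CNF1 was 13 without day 1, 6 without day 7 and 5 without day 30 and its split 1 and 40 after quantile normalization, that of CNF3 against CNF2 was 2 without day 7 and 8 without day 30 with a split of 41 and 15, and that of CNF3 against CNF1 was 2 without day 1 and 1 without day 90. With the common control CNF2 against CNF1 gave 479, CNF3 against CNF1 2147 and CNF3 against CNF2 185 genes. In the first of these Filip1l alone of the named genes kept its call, and in the last Klf15 and Mpp3 did, with Zbtb16 at -0.7 and 0.42. With the 2.0 mg/kg and vehicle arrays alone 1, 0 and 1 genes passed in CNF2 against CNF1, CNF3 against CNF1 and CNF3 against CNF2, and of the named calls only that of Mpp3 was left. Whichever day was left out, Zbtb16 kept its call in CNF2 against CNF1 and Mpp3 in CNF3 against CNF2, and no other named gene did in every such fit. Quantile normalization ended the calls of Msx1, Lzts1, Arhgap20 and Vgll4.

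The vehicles themselves were compared because each material had its own. Among the genes with the smallest p, Camsap2, which caps microtubule minus ends, stood at 0.05 ± 0.11 in CNF1, 0.23 ± 0.1 in CNF2, -0.19 ± 0.1 in CNF3 and 0.48 ± 0.06 in MWCNT vehicle arrays (SD over 5 days; adjusted p = 0.0033 by limma's F test). The apolipoprotein L gene Apol7b stood at -0.49 ± 0.27 in CNF1, 0.04 ± 0.16 in CNF2, -0.68 ± 0.17 in CNF3 and 0.4 ± 0.05 in MWCNT, and Prl8a9, a prolactin family gene, at 0.14 ± 0.42 in CNF1, -0.77 ± 0.57 in CNF2, -1.5 ± 0.2 in CNF3 and 0.24 ± 0.49 in MWCNT. Fgfbp3 had a range of 0.3 between the highest and lowest vehicle mean, Mrpl19, a mitochondrial ribosomal protein gene, 0.38, and Tnrc6b, which acts in silencing by microRNA, 0.33 (adjusted p = 0.0068 for each of these 5). In all 1026 genes passed, 73 of them with a range of at least 1. Glucocorticoid targets were higher in the CNF2 than the CNF1 vehicle (median 0.35, camera adjusted p = 0.0053) and lower in the CNF3 than the CNF2 vehicle (median -0.36, camera adjusted p = 0.00019, and adjusted p = 0.92 with an estimated correlation). Interferon response genes were lower in the MWCNT vehicle than in those of CNF2 (median -0.18, camera adjusted p = 0.00019) and CNF3 (median -0.32, camera adjusted p = 0.00023). Camera called 32 list tests between vehicles at its preset correlation and 0 with an estimated one. The count was 410 without day 1, 3 without day 3, 14 without day 7, 12 without day 30 and 251 without day 90, and 452 after quantile normalization. It was 2 with 3 control-spot factors and 0 with 4, but these fits had fewer than 12 residual degrees of freedom, and lost precision was not told from a removed shift.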

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

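The tests of control spots, of vehicle arrays and of clock genes in this part were chosen only after the results were seen. The random reassignments and the bound of the exact permutations were planned before. The lists for which the permutations are given were picked after their values were seen.

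At 0.5 mg/kg 26315 calls were made over the 4 materials, against 18234 at 2.0 mg/kg. A shift of whole arrays was tested on the 27 spots that hold no rat sequence: 74 of 108 tests passed at 0.5 mg/kg and 0 at 2.0 mg/kg (limma, 11 unadjusted), so such a shift is consistent with the pattern. A response of the lung to 0.5 mg/kg cannot be told apart from it for these genes. With 3 control-spot factors 5554 calls were left at 0.5 mg/kg and with 4 factors of all control spots 15, but the factors follow the dose and the median SE rose from 0.117 to 0.197 and 0.255.

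Interferon response genes were higher after MWCNT than after each cellulose material in the 2.0 mg/kg effect, but with an estimated correlation the adjusted p was 0.42 against CNF1, 0.25 against CNF2, where 0 of 16 members passed, and 0.057 against CNF3. Low values in the MWCNT vehicle arrays alone cannot be told apart from this: in the 2.0 mg/kg arrays themselves MWCNT was still higher by medians of 0.53, 0.37 and 0.5, but with an estimated correlation the adjusted p was 0.76, 0.7 and 0.53. Swings of the whole list between single arrays cannot be told apart from it either. The exact permutation p was 0.0039, the smallest that this test can give, and 0.057 adjusted over 44 lists. That planned bound was not decisive, because the list was picked among 44 after its values were seen.

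Glucocorticoid targets were higher after CNF1 and CNF3 than after CNF2 and MWCNT, in differences that share arrays, and of these CNF1 against MWCNT lost its call with an estimated correlation (adjusted p = 0.14). Lungs taken at different times of day were tested on 12 clock genes other than Per1: their median difference in size between CNF3 and CNF2 was 0.2 (0.05 to 0.88, 0 of 12 past), against 0.84 for the targets (0.01 to 2.14, 5 of 10 past), which argues against that source for the lists as sets, though single genes overlap. Differences between the vehicle arrays alone cannot be told apart from the pattern, since CNF3 minus CNF2 was 0.38 in the 2.0 mg/kg arrays (adjusted p = 0.73 with an estimated correlation) and -0.36 in the vehicles. Swings of the whole list between single arrays stay open too, at an exact permutation p of 0.0015 and 0.066 adjusted over the lists. As with the interferon list, that planned bound was not decisive because the list was picked after its values were seen.

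Differences between groups drew attention in 33 genes for CNF2 against CNF1, 260 for MWCNT against CNF1, 24 for CNF3 against CNF2, 17 for MWCNT against CNF2 and 77 for MWCNT against CNF3. The change from day 1 to day 90 held 14 genes for CNF3 and 26 for MWCNT. Probes without a gene name, 20080 in all, passed at 2.0 mg/kg in 6534 cases for CNF1 (2176 higher and 4358 lower), 4156 for CNF2 (1609 and 2547), 2322 for CNF3 (999 and 1323) and 2639 for MWCNT (993 and 1646). Of 64 control spots outside the spike-in set, 3 passed for CNF1, 1 for CNF2 and 2 for MWCNT.

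Doses were reassigned at random among the 4 arrays of each material and day, and 1 of 100 draws, the real one, gave as many genes for each of the 12 dose effects, so chance can be excluded as their source. The highest other draws at the 3 doses in rising order gave 1935, 2047 and 2626 genes for CNF1, and 3543, 2185 and 1975 for CNF2. They gave 1, 1 and 311 for CNF3, and 4, 29 and 0 for MWCNT, against the real 7558, 5863 and 6631, 8054, 6356 and 4982, 4675, 3949 and 3143, and 6028, 2547 and 3478. Reassigning materials gave as many genes in 1 of 100 draws for CNF2 against CNF1 (33, highest other 10), MWCNT against CNF1 (260 and 28) and MWCNT against CNF3 (77 and 1). Chance can be excluded for these 3. It cannot be for CNF3 against CNF2 (24 and 47) and MWCNT against CNF2 (17 and 26), at 2 of 100. CNF3 against CNF1 gave 0 by limma (1265 unadjusted, highest other 4), which any draw matches, so it stays open. Among the vehicles 1 of 100 draws, the real one, gave 1026 genes (highest other 23).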

How the results depend on the processing

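The tests with factors from the control spots, with the probe of highest mean per gene and without the 0.5 and 1.0 mg/kg arrays were chosen after the data were seen, and the other alternatives before the data were examined. Counts below follow a fixed order: dose responses by day (1, 3, 7, 30 and 90), the change to day 90 by material (CNF1, CNF2, CNF3 and MWCNT) and effects by dose (0.5, 1.0, 2.0 mg/kg). Differences run CNF2 against CNF1, CNF3 against CNF1, MWCNT against CNF1, CNF3 against CNF2, MWCNT against CNF2 and MWCNT against CNF3. Unless a reason is given, the cause was not tested. No paired analysis was possible because each group held 1 array and no number pairs rats across groups, though the dose effects were taken within each material and day, and the vehicles within days. A filter on dim probes and a block for slide or scan were not run, since the files give neither, and the series table held the same values as the single files.

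Quantile normalization gave 0, 565, 277, 10 and 0 genes for CNF1 and 0, 0, 10, 68 and 0 for CNF2. It gave 2, 12, 8, 208 and 3 for CNF3 and 2, 1, 9, 39 and 81 for MWCNT. After it the change to day 90 gave 0, 0, 0 and 1. The effects gave 7848, 5259 and 4035 for CNF1, 8716, 8356 and 4409 for CNF2, 6715, 6102 and 4754 for CNF3 and 6794, 4407 and 3252 for MWCNT. The 6 differences between materials gave 41, 0, 22, 56, 9 and 144, and the vehicles 452. Of the 175 named gene results 84 lost their call with it. Testing every probe, which raises the number of tests, gave 1434, 10244, 1343, 193 and 6 genes for CNF1 and 80, 1280, 60, 55 and 12 for CNF2. This gave 217, 22, 9, 179 and 32 for CNF3 and 28, 0, 8, 50 and 422 for MWCNT. With probes the change to day 90 gave 0, 0, 5 and 32. The effects gave 19939, 14311 and 15360 for CNF1, 20929, 15873 and 10417 for CNF2, 12448, 9152 and 5977 for CNF3 and 15740, 5571 and 6627 for MWCNT. Between materials the counts were 74, 0, 452, 52, 33 and 90, and the vehicles 3140.

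A fold of at least 2 added to the adjusted p, a stricter threshold, gave 338, 2118, 478, 15 and 2 genes for CNF1 and 48, 429, 49, 45 and 7 for CNF2. The stricter threshold gave 96, 16, 5, 94 and 21 for CNF3 and 18, 0, 18, 33 and 198 for MWCNT. With it the change to day 90 gave 0, 0, 14 and 25. The effects gave 1379, 499 and 512 for CNF1, 1795, 1626 and 380 for CNF2, 799, 904 and 243 for CNF3 and 1081, 510 and 256 for MWCNT. Material differences numbered 6, 0, 48, 8, 11 and 30, and the vehicles 73. Taking the probe with the highest mean for each gene moved CNF3 on day 7 from 5 to 9, MWCNT on day 1 from 23 to 37 and MWCNT on day 3 from 0 to 3 genes, and no other count by over 1.5 times. It ended the calls of Mboat2 (CNF2, day 30), Sfrp2 and Nostrin (CNF3, day 30), Sectm1a (MWCNT, day 7), Gfra3 and Il18 (MWCNT, day 90 against day 1) and Arhgap20 (CNF2 against CNF1).

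With 3 factors of the control spots the dose response gave 327, 5960, 2152, 160 and 15 genes for CNF1 and 212, 1662, 336, 235 and 90 for CNF2. These factors gave 681, 116, 60, 361 and 120 for CNF3 and 128, 44, 178, 283 and 893 for MWCNT. With them the change to day 90 gave 0, 32, 32 and 113. The effects gave 535, 490 and 6151 for CNF1, 1884, 131 and 4381 for CNF2, 2899, 1092 and 3120 for CNF3 and 236, 0 and 3838 for MWCNT. The differences gave 49, 0, 320, 31, 20 and 109, and the vehicles 2. With 4 factors of all control spots the counts were 621, 6673, 2737, 285 and 16 genes for CNF1 and 489, 1963, 490, 355 and 117 for CNF2. They were 1257, 155, 121, 476 and 156 for CNF3 and 239, 49, 352, 465 and 1256 for MWCNT. For these factors the change to day 90 gave 26, 69, 53 and 170. The effects gave 2, 0 and 5673 for CNF1, 0, 3 and 4196 for CNF2, 10, 337 and 2752 for CNF3 and 3, 0 and 4080 for MWCNT. For pairs of materials there were 53, 0, 206, 31, 25 and 108, and the vehicles 0.

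A common control, the mean of the 4 vehicles, gave 3510, 6671, 3423, 412 and 1 genes for CNF1 and 2180, 4822, 1605, 451 and 171 for CNF2. That control gave 1366, 361, 258, 686 and 296 for CNF3 and 701, 131, 716, 726 and 1699 for MWCNT. With it the change to day 90 gave 334, 232, 129 and 193. The effects gave 8762, 7384 and 8329 for CNF1, 9666, 7905 and 7069 for CNF2, 7377, 6960 and 5064 for CNF3 and 7939, 3217 and 5354 for MWCNT. Pairs of materials gave 479, 2147, 3815, 185, 791 and 940. Fitting each material alone, with fewer arrays, gave 3, 2666, 123, 1 and 0 genes for CNF1 and 1, 8, 1, 6 and 0 for CNF2. Alone, the fits gave 70, 1, 0, 30 and 5 for CNF3 and 7, 1, 0, 20 and 361 for MWCNT. In these fits the change to day 90 gave 0, 0, 1 and 14. The effects gave 4830, 2082 and 3994 for CNF1, 7671, 5762 and 4398 for CNF2, 5008, 3901 and 3416 for CNF3 and 7263, 4004 and 4513 for MWCNT.

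Dose as a rank gave 1128, 4544, 1047, 66 and 2 genes for CNF1 and 170, 1227, 168, 79 and 4 for CNF2. Ranks gave 285, 60, 39, 207 and 49 for CNF3 and 65, 3, 35, 62 and 380 for MWCNT. With ranks the change to day 90 gave 7, 4, 23 and 19. The mean of the 3 exposed arrays against the vehicle, which ignores the order of doses, gave 376, 2700, 60, 4 and 1 genes for CNF1 and 116, 1878, 163, 11 and 0 for CNF2. The mean gave 101, 4, 0, 11 and 1 for CNF3 and 18, 14, 6, 3 and 24 for MWCNT. With the mean the change to day 90 gave 0, 2, 0 and 4. Without the 0.5 and 1.0 mg/kg arrays, a fit with fewer arrays, the 2.0 mg/kg effects gave 5609, 3409, 1402 and 1866 and the differences 1, 0, 1, 1, 0 and 1.

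Leaving out the arrays of 1 dose, which removes arrays, gave dose-response counts of 65 to 831, 2331 to 4025, 154 to 645, 1 to 6 and 0 to 0 for CNF1. For CNF2 they were 23 to 166, 3 to 2240, 2 to 145, 1 to 35 and 0 to 5. For CNF3 they ran 3 to 231, 5 to 8, 0 to 5, 27 to 136 and 6 to 16, and for MWCNT 3 to 46, 0 to 2, 1 to 9, 3 to 13 and 9 to 206. The change to day 90 gave 1 to 2, 0 to 3, 0 to 10 and 0 to 17. The slope of Gpr25 in the MWCNT dose response on day 30 ran from -0.12 without 2.0 mg/kg to 1.93 without 1.0 mg/kg. Leaving out 1 day gave effects of 5993 to 7812, 3133 to 6896 and 4631 to 7367 for CNF1. CNF2 gave 6303 to 8530, 4452 to 7438 and 2762 to 5784. CNF3 gave 2046 to 4795, 1633 to 5411 and 1452 to 3512. MWCNT gave 4431 to 5699, 735 to 3546 and 2120 to 3276. The differences gave 5 to 31, 0 to 2, 19 to 668, 2 to 26, 3 to 31 and 10 to 142, and the vehicles 3 to 410.

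The count of calls moved past 1.5 times in 3 of the 43 results with the probe of highest mean, 23 with every probe, 26 with a fold of 2, 27 with quantile normalization, 31 with 3 control-spot factors and 34 with 4. It did so in 34 of 42 with a common control, 25 of 36 for materials alone, 14 of 24 with ranks, 22 of 24 with the mean of 3 arrays and 7 of 10 without the 0.5 and 1.0 mg/kg arrays. Leaving out 0.5, 1.0 or 2.0 mg/kg moved 15, 22 and 22 of 24, and leaving out days 1, 3, 7, 30 or 90 moved 10, 5, 9, 10 and 5 of 19. Of the 100 named dose-response results 41, 70 and 85, besides Gpr25, lost their call without 0.5, 1.0 or 2.0 mg/kg. With the mean of 3 arrays 76 did. Only Gpr25 reversed under the alternatives run. With an estimated correlation in place of the preset 0.01, 380 list tests lost their call, while with fry 242 lost and 47 gained 1, and with 3 control-spot factors 23 lost and 77 gained 1. Values without signal over background left no way to tell weak probes from absent transcripts, so the falls of receptor genes could not be graded by signal.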

Other observations

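The tests of contrasts in this part were chosen only after the results were seen. At 2.0 mg/kg over 5 days, with values in the order CNF1, CNF2, CNF3 and MWCNT, Slc7a11, the cystine transporter used to make glutathione, rose by 3.4, 4.15, 3.92 and 1.67 (SE 0.56). Hmox1, which breaks down haem, rose by 1.2, 1.21, 1.3 and 1.1 (SE 0.18). Gsta4, a glutathione transferase, stood at -0.91, -0.7, -0.52 and -0.53 (SE 0.15). The chemokine genes Ccl17, which attracts T cells, and Ccl22 rose by 2.54, 2.17, 1.54 and 2.04 (SE 0.44), and by 2.22, 2.49, 1.78 and 2.02 (SE 0.42). Retnla, a marker of type 2 inflammation, rose by 2.81, 2.53, 2.66 and 2.8 (SE 0.42). Their lists moved less. The 5-day means of list medians were 0.08 to 0.12 for oxidative stress. For type 2 chemokines they were 0.22 (MWCNT) to 1.06 (CNF2), and for alarmins and type 2 cytokines 0.12 (MWCNT) to 0.76 (CNF2).

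The clock repressor gene Bhlhe41 rose by 2.24 ± 0.22, 2.19 ± 0.22, 2 ± 0.22 and 1.34 ± 0.22. Decorin (Dcn), a proteoglycan of fibroblasts, fell in each material (-1.09 ± 0.13, -0.82 ± 0.13, -1.1 ± 0.13 and -0.88 ± 0.13). The largest adjusted p of these 8 genes was 0.026.

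Dose responses were also compared between days and materials. The slope on day 90 minus that on day 3 passed for 1240 genes after CNF1 (508 higher and 732 lower), 2 after CNF2, 8 after CNF3 and 2 after MWCNT. On day 3 the slope of MWCNT minus that of CNF1 passed for 410 genes (207 and 203), that against CNF2 for 0 by limma (391 unadjusted) and that against CNF3 for 1. The 1240 and 410 rest on the CNF1 slope of day 3, whose count fell with quantile normalization. On day 90 the slope of MWCNT differed from CNF1 in 16 genes, from CNF2 in 7 and from CNF3 in 20. With 3 control-spot factors the changes from day 3 to day 90 numbered 2574, 26, 14 and 22, and the differences of MWCNT 977, 0 and 1 on day 3 and 60, 47 and 72 on day 90.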
